A study of Glycine max with 4 samples.

How the data were processed

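RNA sequencing libraries were made from 4 samples of Williams 82 soybean: cotyledons of mid-maturation (B1) and late-maturation (AA1) embryos, whole dry seeds, and cotyledons of seedlings 6 days after imbibition. Per the labels' protocols, total RNA was treated with DNase, poly-A RNA was selected in 2 rounds on oligo-dT beads, and 100 ng was fragmented and copied with random primers. Fragments of about 200 bp were amplified for 15 PCR cycles and read once over 76 bp on an Illumina Genome Analyzer IIx. Per the labels' protocol, this is a double-stranded cDNA preparation with no step that marks strand, so reads of a gene and an overlapping antisense gene cannot be separated. The labels name no molecular identifiers, so PCR copies count as separate reads.

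Per the file headers, the deposited files give for each gene model the number of mapped reads, as raw counts with no normalization. All values were whole numbers at or above 0, and the files listed the same 66210 gene models in the same order. Bowtie is named in the submitters' processing notes, without a version. The genome build, the annotation release, the treatment of reads that map to several places and the counting program are not given in the sources used here. Soybean has many near-identical gene copies, so counts of such copies may have been split, dropped or added to each other, depending on that treatment, and values of single gene models are uncertain to that extent. 0 rows lacked a gene identifier. The counts are not corrected for gene length, so levels of different gene models within a library are not compared as molecule numbers.

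The 66210 identifiers were compared with the gene, locus and symbol columns and synonyms of a table of 59048 genes of assembly Glycine_max_v4.0. The number of matches was 0. The 28 gene lists fixed before the data were examined were keyword searches of product descriptions, among them lists of storage proteins, photosystems, chromatin factors and markers of seed coat and embryo axis. They were not run, and gene names, gene structures and coordinates are not used here. The chromosome number and the order along it were read from the identifiers, by the naming convention of soybean gene models. 65781 identifiers carry a chromosome number.

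Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over the 4 libraries. The factors were 0.581 for B1, 1.05 for AA1, 1.08 for dry seed and 1.51 for seedling cotyledons. Scaled CPM is the count divided by the scaled library size, times 1000000. For each pair of libraries, gene models with at least 1 scaled CPM in either library entered. Counts under 3 were set to 3 before the ratio was taken for ranking and for counting gene models at least 4-fold apart. This floor corresponds to 0.32 scaled CPM in B1, 0.07 in AA1, 0.13 in dry seed and 0.07 in seedling cotyledons, so low levels are least resolved in B1. Folds printed for single gene models are ratios of unfloored scaled CPM, with exact 95% intervals from the binomial distribution of the 2 counts. Shares of counts have exact Clopper-Pearson 95% intervals. All of these cover counting error only. With 1 library per stage no test across samples is possible. Being at least 4-fold apart is therefore a rule of size that compares 2 libraries, and the stage cannot be told apart from a difference between library preparations.

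The rule for naming gene models was fixed before the data were examined. With no match to a name table, it gives for each of the 3 consecutive steps the 2 gene models with the largest fold higher and the 2 with the largest fold lower among those with at least 50 scaled CPM in the higher library. The most extreme folds were thus picked, so printed folds tend to be too large, and their intervals do not allow for the choice. Stage groups required a gene model's unfloored level in every high library to be at least 4-fold above its floored level in every other library. The groups of 2 or 3 high libraries, the comparison of 2 steps and the chromosome sums were added after the data were seen. Alternatives fixed beforehand were 4 other scalings (total counts, DESeq2 1.42.0 size factors, the upper quartile, and totals without the 100 most abundant genes of any library), other entry filters, a pseudocount of 1 scaled CPM, the interval rule, and thinning of all libraries to 16120894 counts.

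The procedure was tested on simulated data for each step, with counts of 66210 gene models drawn from the mean profile of the 2 libraries. For AA1 against B1, 99 of 100 gene models changed 8-fold were recovered in the right direction, 0 of 100 changed 2-fold were called 4-fold apart, and 6 of 26140 unchanged ones were called. For dry seed against AA1, 100 of 100 were recovered and 0 of 25363 unchanged ones were called. For seedling against dry seed, 100 of 100 were recovered and 0 of 30287 unchanged ones were called. These simulations hold counting error only and no variation between plants. Apart from the changed gene models, both simulated libraries followed the same mean profile. An error of scaling between pools of different composition was therefore not tested. For AA1 against B1, low levels in B1 were better resolved in the simulation than in the data. The numbers of unchanged gene models called cover counting error alone and give no rate of false calls for the real comparisons.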

Results

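Polyadenylated RNA of the soybean cultivar Williams 82 was sequenced at 4 points between seed filling and early seedling growth. The cotyledon is the embryonic leaf that fills most of the soybean seed and stores its reserves. Cotyledons of mid-maturation embryos (stage B1) were green and a pair weighed 150 to 250 mg. Cotyledons of late-maturation embryos (stage AA1) were yellow and a pair weighed 200 to 350 mg. Whole dry seeds weighed 100 to 250 mg and contained a small contribution of seed coat and axis besides the cotyledons. Cotyledons of seedlings were taken 6 days after imbibition. Each of the 4 stages was represented by 1 library, so a difference between stages has no replicate check and no p-value is given. The deposited files held whole-number counts of mapped reads for 66210 gene models. Totals were 16120894 counts for B1, 38011608 for AA1, 21512278 for dry seed and 28190429 for seedling cotyledons. Of the gene models, 17904 had no count in any of the 4 libraries. None of the identifiers matched an entry of the gene name table at hand, so gene models are given by identifier and described as groups by their stage profile, without product names. Intervals are 95% intervals and cover counting error only. Those of named gene models do not allow for the choice of the most extreme folds.

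By the 10 and 100 most abundant gene models, the transcript pool was most concentrated in the mid-maturation cotyledon and least in the seedling cotyledon. The 10 most abundant gene models took 45.0% of the counts in B1 (exact binomial interval 44.97% to 45.02%), 16.1% in AA1 (16.12% to 16.15%), 11.3% in dry seed (11.26% to 11.29%) and 7.68% in seedling cotyledons (7.668% to 7.688%). The 100 most abundant took 70.9%, 38.9%, 29.8% and 20.6%, in the same order. A single gene model held 12.1% of the B1 counts, against 3.39%, 2.24% and 2.46% for the most abundant one of AA1, dry seed and seedling. By this measure dry seed was the least concentrated. In B1, 14 gene models were enough to reach 50% of all counts. The corresponding numbers were 313 in AA1, 776 in dry seed and 1531 in seedling cotyledons. The differences in the shares of the 1, 10 and 100 most abundant gene models exceeded their counting intervals. At these depths such intervals are narrow, and they hold no variation between plants or preparations. No interval was computed for the numbers that reach 50%.

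**Figure D1:**
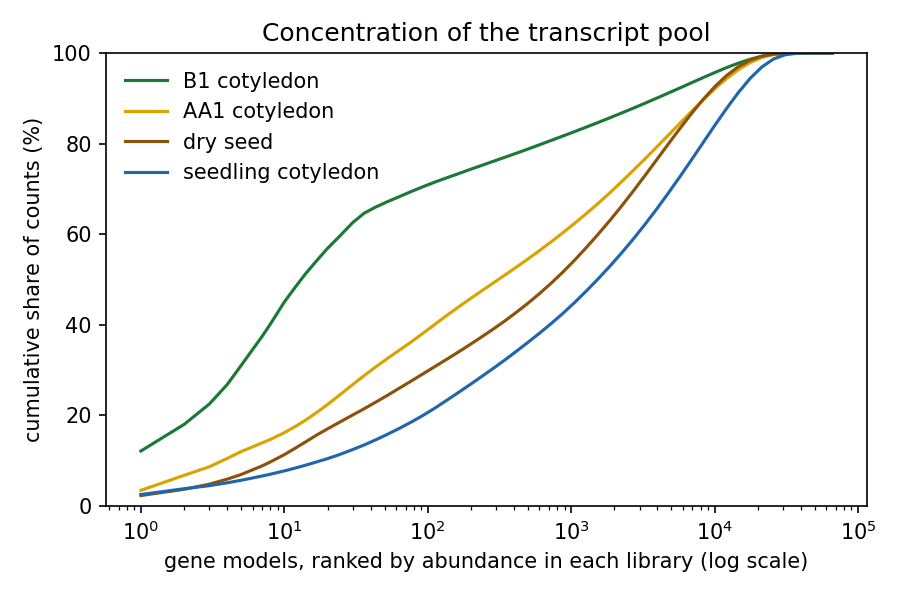
Cumulative share of counts (percent, vertical axis) against the number of gene models, ranked by abundance within each library (log scale, horizontal axis), with 1 line per library. The B1 line reaches 45.0% at 10 gene models, and the seedling line reaches 7.68%.

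The abundant transcripts of the seed stages were followed into the other libraries. The 100 gene models most abundant in B1 held 70.9% of counts in B1, 28.6% in AA1, 16.6% in dry seed and 1.84% in seedling cotyledons. The 100 most abundant in dry seed held 27.9% in B1, 36.2% in AA1, 29.8% in dry seed and 2.40% in seedlings. The 100 most abundant in seedling cotyledons held 2.19% in B1, 3.04% in AA1, 2.55% in dry seed and 20.6% in seedlings. B1 and AA1 shared 51 of their 100 most abundant gene models, AA1 and dry seed shared 71, and dry seed and seedling shared 9. Of the 10 most abundant in seedling cotyledons, 0 were among the 10 most abundant of any seed library, while AA1 and dry seed had 7 in common. Each list was chosen for its abundance in 1 library, so its share is favoured in that library.

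**Figure D2:**
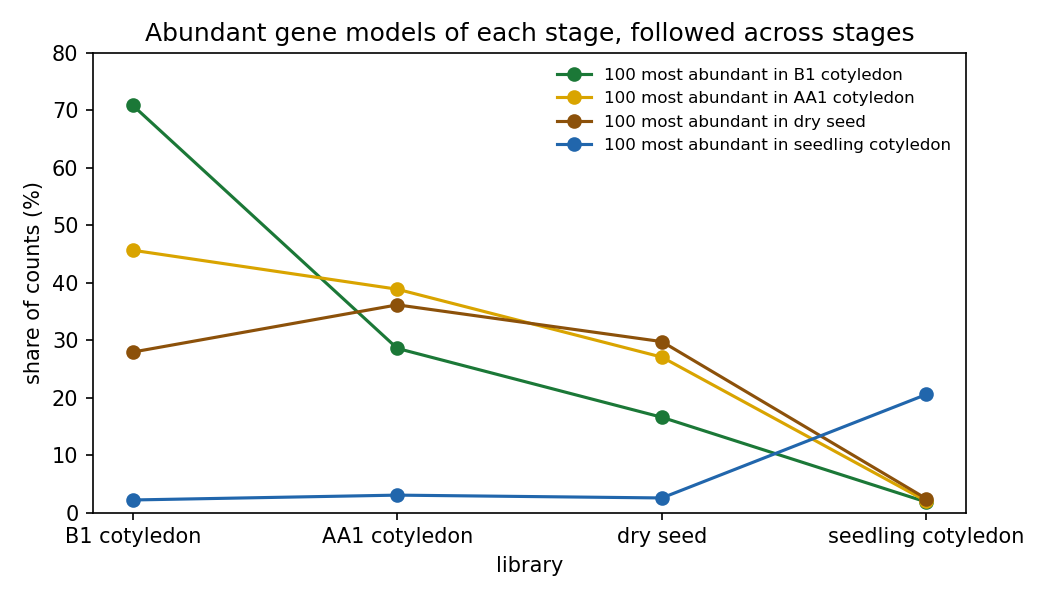
Share of all counts (percent, vertical axis) held in each of the 4 libraries (horizontal axis) by the 100 gene models most abundant in 1 library; each line is 1 such list. The 3 lists from seed libraries lie between 1.84% and 2.40% in the seedling library, and the seedling list lies between 2.19% and 3.04% in the seed libraries.

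The largest number of gene models was detected in the seedling cotyledon library. At 1 CPM (count scaled to a common library size) or more, 30961 gene models were detected in seedling cotyledons, 25199 in AA1, 23608 in dry seed and 23312 in B1. A CPM threshold is already scaled to depth. The number of gene models with any count depends on depth, and after each library was thinned to the depth of B1 it was 43000, 37750, 37001 and 37120, in the same order. The 1 CPM threshold is stricter for the less abundant transcripts of B1, where a few gene models take most counts. With library sizes scaled by TMM (trimmed mean of M-values), 26316 gene models reached 1 scaled CPM in B1, 24973 in AA1, 23194 in dry seed and 29062 in seedling cotyledons. Hence B1 had the lowest number of the 4 under plain CPM and the second highest under scaled CPM.

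Late-maturation and dry-seed transcript pools resembled each other most. Across gene models, the Pearson correlation of log2(scaled CPM + 1) between AA1 and dry seed was 0.943 and the Spearman correlation 0.923. B1 and AA1 correlated at 0.851 and 0.881, and B1 and dry seed at 0.778 and 0.840. Seedling cotyledons correlated with B1 at 0.751 and 0.839, with AA1 at 0.767 and 0.863, and with dry seed at 0.718 and 0.818. These correlations run across all 66210 gene models, 17904 of which had no count in any library. Many others are low in both libraries, and genes are not independent replicates. With 10 in place of 1 added to each value, which gives low levels less weight, the Pearson correlation was 0.920 for AA1 with dry seed, 0.793 for B1 with AA1 and 0.681 for B1 with dry seed. It was 0.593, 0.625 and 0.580 for seedling cotyledons with B1, AA1 and dry seed. A filter of at least 10 scaled CPM in either library gave 0.706 for AA1 with dry seed. B1 then correlated at 0.366 with AA1 and 0.139 with dry seed. Seedling cotyledons then correlated at -0.039 with B1, -0.009 with AA1 and -0.079 with dry seed. Such a filter itself lowers a correlation, since it drops gene models low in both libraries.

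The first step compared late-maturation with mid-maturation cotyledons, as the green embryo turned yellow. Of 29154 gene models with at least 1 scaled CPM in either library, 3836 were at least 4-fold higher in AA1 and 4828 at least 4-fold lower. The lower group held 61.8% of the counts in B1 and 5.94% in AA1. The higher group held 2.10% in B1 and 29.6% in AA1. Here, and in the comparisons and stage groups below, members were chosen by their levels in these same libraries. The direction of a change in such a share therefore follows from that choice. A distance of at least 100-fold was reached by 247 gene models of the lower group and 51 of the higher group. The floor of 3 counts is 0.32 scaled CPM in B1 and 0.07 in AA1. A 100-fold rise therefore needs a higher level in AA1 than a 100-fold fall needs in B1. Glyma03g29440 was 815-fold higher in AA1 (interval 611 to 1113), with 4.91 scaled CPM in B1 and 4003 in AA1. It stayed at 6793 in dry seed and stood at 31.8 in seedling cotyledons. Glyma07g02660 was 602-fold higher in AA1 (206 to 2918, from 3 counts in B1), and its scaled CPM was 193 in AA1, 447 in dry seed and 23.6 in seedlings. Glyma08g45480 was 2549-fold lower in AA1 (1293 to 5907), with 509 scaled CPM in B1 and 0.20 in AA1. Glyma08g40260 was 1757-fold lower (1137 to 2878), with 877 scaled CPM in B1 and 0.50 in AA1. These folds depend on the scaling, because the B1 pool is dominated by few transcripts. The higher share among gene models 4-fold apart was 44.3% with TMM and 75.1% with total counts, under which the median gene model was itself 1.15 higher in AA1 on the log2 scale (0.19 with TMM). DESeq2 size factors, the upper quartile and totals without the 100 most abundant genes gave 37.3%, 37.3% and 36.1%. At 2-fold more were higher than lower (9074, 8046), and with a pseudocount of 1 scaled CPM 2238 were higher and 2488 lower. The unequal floor also bears on this balance. A gene model at 1 scaled CPM in AA1 cannot be called 4-fold higher, while one at 1 in B1 can be called lower. Requiring 5 scaled CPM left 2700 higher and 2763 lower. No filter beyond more than 3 counts in either library gave 3836 higher and 6104 lower.

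The second step compared whole dry seeds with late-maturation cotyledons. It was the smallest of the 6 pairwise comparisons: of 26397 gene models, 1574 were at least 4-fold higher in dry seed and 2575 at least 4-fold lower, together 15.7%. The higher group held 1.05% of AA1 counts and 6.91% of dry-seed counts, and the lower group held 10.2% and 1.68%. The 100-fold distance was passed by 26 gene models of the higher group and 0 of the lower group. The floor of 3 counts is 0.07 scaled CPM in AA1 and 0.13 in dry seed. A 100-fold fall therefore needs a higher level in AA1 than a 100-fold rise needs in dry seed. Glyma02g10320 had 2 counts in AA1 and 1640 in dry seed, a 1410-fold ratio (390 to 11650), and stood at 3.76 scaled CPM in seedlings with 0 counts in B1. Glyma18g52170 was 177-fold higher in dry seed (130 to 249), with 0.998 scaled CPM in AA1, 177 in dry seed and 0.92 in seedlings. Glyma15g42500 was 24.7-fold lower in dry seed (18.9 to 32.8), with 59.4 scaled CPM in AA1 and 2.40 in dry seed. Glyma02g34670 was 24.0-fold lower (19.1 to 30.7), with 76.3 and 3.18 scaled CPM. The dry-seed library alone contained seed coat and axis, so tissue and stage differ together in each comparison with dry seed. When the 4-fold distance was required of the interval bound nearest to 1, 1048 gene models were higher and 1240 lower, and a filter of 5 scaled CPM left 916 higher and 1065 lower. With a pseudocount of 1 scaled CPM the balance turned (718 higher, 712 lower).

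The third step compared seedling cotyledons with whole dry seeds, which differ in tissue (seed coat and axis) as well as in stage. It was the largest of the 6 comparisons with TMM scaling: of 31169 gene models, 9813 were at least 4-fold higher in seedlings and 4882 at least 4-fold lower, together 47.1%. With total counts it came second, at 15530 gene models against 16903 for seedling against B1. The higher group held 1.69% of counts in dry seed and 52.8% in seedling cotyledons, and 1934 of its members had 0 counts in dry seed. The lower group held 60.6% in dry seed and 6.07% in seedlings. At least 100-fold distances were found for 1041 gene models of the higher group and 222 of the lower group. Glyma07g01730 was 22060-fold higher in seedlings (11620 to 48230, from 9 counts in dry seed) and reached 8521 scaled CPM, against 2.24 in B1 and 0.07 in AA1. Glyma07g13780 was 13380-fold higher (5227 to 49120, from 4 counts) and reached 2298 scaled CPM. Glyma18g43320 was 1071-fold lower in seedlings (754 to 1577), with 285 scaled CPM in B1, 740 in AA1, 781 in dry seed and 0.73 in seedlings. Glyma08g22630 was 971-fold lower (819 to 1160), with 18.2 scaled CPM in B1, 307 in AA1, 3038 in dry seed and 3.13 in seedlings. The higher share among gene models 4-fold apart was 66.8% with TMM and 78.0% with total counts, under which the median gene model was 0.90 higher in seedlings on the log2 scale (0.32 with TMM). DESeq2 size factors, the upper quartile and totals without the 100 most abundant genes gave 63.2%, 60.8% and 73.5%. With a filter of 5 scaled CPM the share was 60.4%, and the median was -0.06 on the log2 scale. The pseudocount gave 5952 higher and 3418 lower.

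The remaining pairs set distant stages side by side. Seedling cotyledons had 7157 gene models at least 4-fold higher and 3737 at least 4-fold lower than B1. The lower group held 80.9% of B1 counts and 3.73% of seedling counts. Against AA1, 7715 gene models were at least 4-fold higher in seedlings and 3329 lower. Total counts gave 10247 higher and 2209 lower for this pair, and the pseudocount gave 4574 and 2150. Whole dry seed, with its seed coat and axis, had 5841 gene models at least 4-fold higher and 7003 at least 4-fold lower than B1, and the lower group went from 75.5% of B1 counts to 6.02% of dry-seed counts. The higher share depended on scaling in all 3 pairs. It was 65.7%, 69.9% and 45.5% with TMM and 91.0%, 82.3% and 69.4% with total counts. With the upper quartile it was 52.7% for seedling against B1 and 61.65% for seedling against AA1. With totals without the 100 most abundant genes it was 33.2% for dry seed against B1. For dry seed against B1 more were also higher with a filter of 5 scaled CPM (4728, 4114), with the pseudocount (4166, 3943) and at 2-fold (10353, 10078). The floor of 3 counts is 0.32 scaled CPM in B1 and 0.13 in dry seed. It therefore limits calls of higher more than calls of lower in that pair.

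**Figure D3:**
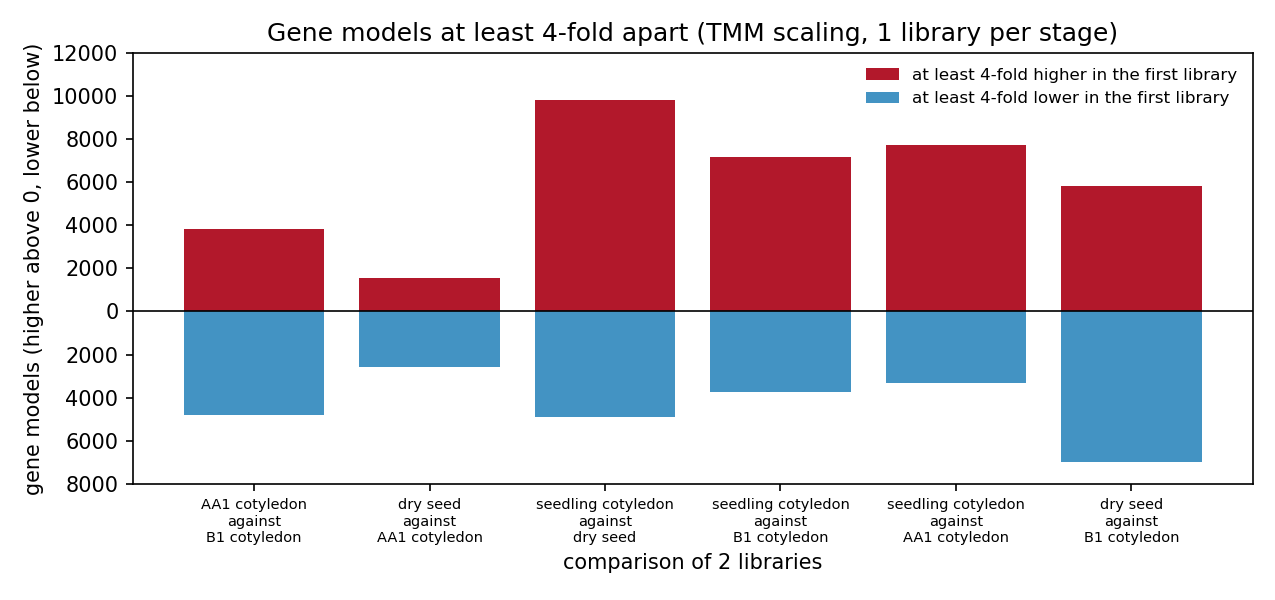
Number of gene models at least 4-fold higher (above 0) or lower (below 0) in the first library of each of the 6 comparisons, with TMM scaling and 1 library per stage. The step from dry seed to seedling has 9813 higher and 4882 lower, and the step from AA1 to dry seed has 1574 and 2575.

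Gene models were then grouped by the libraries in which they stood at least 4-fold above all others, out of 33358 with at least 1 scaled CPM in some library. The largest group was the 4181 gene models highest in seedling cotyledons, with median levels of 11.2 scaled CPM in seedlings, 0.43 in B1, 0.30 in AA1 and 0.13 in dry seed. They held 39.1% of seedling counts and 0.63% to 0.90% of the counts of the seed libraries. B1 was the highest stage for 1623 gene models, which held 58.9% of B1 counts, 5.36% of AA1, 1.59% of dry seed and 0.80% of seedling counts. Dry seed was the highest stage for 800, which held 5.72% of its counts. AA1 was the highest for 160, which held 1.03% of its counts. With total counts in place of TMM, 7153 gene models were highest in seedlings and 726 in B1.

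Several groups were shared between stages. The 2408 gene models high in both B1 and seedling cotyledons and low in AA1 and dry seed had medians of 4.81, 0.25, 0.13 and 7.38 scaled CPM in B1, AA1, dry seed and seedlings. They held 2.52% of B1 counts, 0.28% of AA1, 0.13% of dry-seed and 17.9% of seedling counts. The opposite group, high in AA1 and dry seed, had 762 members with medians of 2.88, 31, 50.1 and 2.63 scaled CPM, and held 0.81%, 15.2%, 18.8% and 0.87% of counts. The 1120 gene models high in all 3 seed libraries held 69.7%, 43.3% and 31.2% of B1, AA1 and dry-seed counts and 1.02% of seedling counts. With total counts this group had 576 members. The 1501 gene models at least 4-fold lower in dry seed than in every other library had a median of 0.26 scaled CPM there. Their medians were 6.62, 1.97 and 8.07 in B1, AA1 and seedlings, so AA1 was intermediate. The 1153 low only in B1 had a median of 0.96 there and 13.5, 17.6 and 16.2 in AA1, dry seed and seedlings. That last count was 4054 with total counts and was 877 to 974 with the other scalings. B1 and dry seed together against AA1 and seedling gave 66, and dry seed with seedling against B1 and AA1 gave 130. With total counts these were 35 and 310. The floor of 3 counts is highest in B1, at 0.32 scaled CPM. Groups low in B1 therefore need higher levels to be called than groups high in B1, so their sizes are not directly comparable. With at least 10 scaled CPM in some library, 1202 of the 2408 and 614 of the 762 remained. So did 751 of the 1623 highest in B1, 840 of the 1120 and 931 of the 1153. In total, 12486 gene models (37.4%) entered at least 1 group, and some entered more than 1. The shares of counts held by different groups therefore overlap and cannot be added. Libraries drawn from a common profile with counting error alone gave 0 gene models in each of the 14 groups. All 4 drawn libraries had the same composition, so low levels in B1 were better resolved in the draw than in the data. The draw held no variation between plants or preparations.

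**Figure D4:**
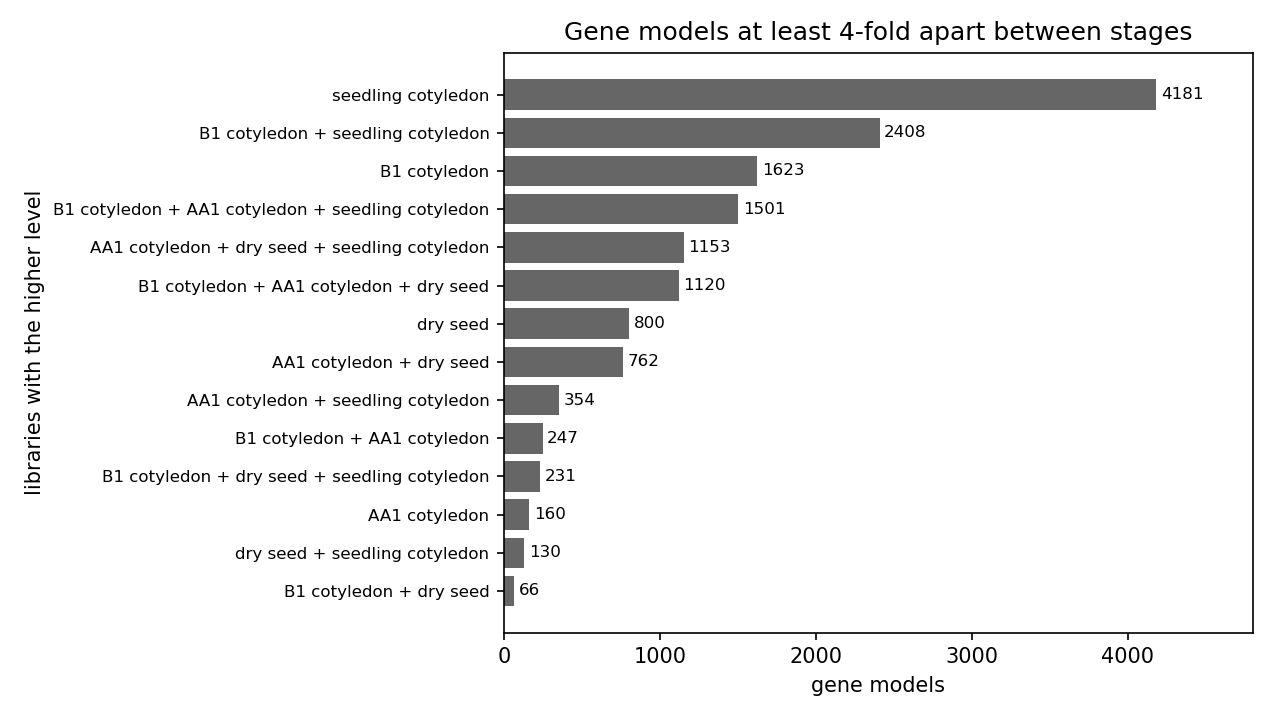
Number of gene models (horizontal axis) whose level in every library named on the vertical axis was at least 4-fold above their level in every other library, with TMM scaling. The bars run from 66 for B1 with dry seed to 4181 for seedling cotyledons alone.

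Whether transcripts that differed between the maturation stages differed in the opposite direction between dry seed and seedling was asked with 2 comparisons that share no library, AA1 against B1 and seedling against dry seed. Of 4828 gene models at least 4-fold lower in AA1 than in B1, 2604 (53.9%) were at least 4-fold higher in seedling than in dry seed, against 23.0% of all 29154 gene models of the first comparison, a ratio of 2.35. Of 3836 gene models higher in AA1, 1342 (35.0%) were lower in seedling than in dry seed, against 15.0% of all, a ratio of 2.33. The same-direction overlaps were below independence: 613 against 881 for higher in both, and 163 against 726 for lower in both. A call of lower in seedling needs at least 1 scaled CPM in dry seed. Gene models low in AA1 tend to be low in dry seed too, so 726 is not a neutral baseline. Low levels in dry seed also leave more room for a call of higher in seedling. Gene models high in AA1 tend to be high in dry seed, which favours a call of lower in seedling. The 23.0% and 15.0% of all gene models, and the 881, are therefore not neutral baselines either. Of the 4828, 1283 were under 1 scaled CPM in both dry seed and seedling and are counted here as neither higher nor lower. Leaving them out gives 73.5% in place of 53.9%, a share that the entry filter favours, since a gene model low in dry seed then enters only through its seedling level. Across the 4 other scalings the first ratio was 2.18 to 2.38 and the second 2.06 to 2.70. AA1 and dry seed resemble each other, so the comparisons are not independent even though they share no library, and dry seed alone held seed coat and axis. Gene models are not independent, so these ratios describe these 4 libraries.

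Soybean identifiers carry a chromosome number, which allowed the counts to be summed by chromosome. Chromosome 13 held 18.2% of B1 counts, against 6.66% in AA1, 6.75% in dry seed and 6.21% in seedling cotyledons. Chromosome 10 held 12.8%, 9.21%, 6.80% and 4.97%, and chromosome 3 held 9.19%, 10.3%, 7.52% and 4.24%. Chromosome 8 held 10.9% in B1 and 9.49% in seedlings, against 5.81% in AA1 and 6.66% in dry seed. Others were lowest in B1: chromosome 17 held 2.21%, 7.25%, 8.39% and 5.57%, and chromosome 9 held 2.94%, 7.16%, 6.22% and 4.84%. These differences rested on few gene models. Without the 264 gene models that were among the 100 most abundant of any library, chromosome 13 held 6.00%, 6.16%, 5.93% and 5.61%, chromosome 10 held 5.46%, 5.34%, 5.37% and 5.61%, and chromosome 17 held 5.15%, 4.88%, 5.05% and 5.44%.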

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

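The groups high in 2 or 3 libraries, the thinned and further scalings of the stage groups, the single entry filter for the 2-step overlap, and detection at scaled CPM were chosen after the data were seen. Of 267 recomputed values of the main results, 200 stayed within 1.5 times (for correlations, close to the original), and 67 moved further. The balance between higher and lower gene models turned in 7 of 66 recomputed balances. For AA1 against B1 more were lower (3836 higher, 4828 lower), but more were higher with total counts (8216, 2727) and at 2-fold (9074, 8046). For dry seed against B1 (5841 higher, 7003 lower) more were higher with total counts (9976, 4392), with 5 scaled CPM (4728, 4114), with the pseudocount (4166, 3943) and at 2-fold (10353, 10078). For dry seed against AA1 (1574 higher, 2575 lower) the pseudocount gave 718 and 712. Among 48 recomputed folds of named gene models, 4 moved beyond their counting interval and all kept their direction. Dry seed against AA1 had the fewest gene models 4-fold apart of the 6 pairs under each alternative run, and seedling against dry seed had the most under each except total counts.

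Of the main results, total counts moved 16 of 32 recomputed values and the pseudocount 16 of 18. Total counts gave 8216 higher and 2727 lower for AA1 against B1. They gave 16903 apart (15379 higher, 1524 lower) for seedling against B1, 9976 higher and 4392 lower for dry seed against B1, and 2209 lower for seedling against AA1. Stage groups under total counts were 726 for B1, 7153 for seedling, 4054 for AA1 with dry seed and seedling, 675 for AA1 with seedling, 576 for the 3 seed libraries, 162 for B1 with AA1, 35 for B1 with dry seed and 310 for dry seed with seedling. DESeq2 size factors, the upper quartile and totals without the 100 most abundant genes left every count within 1.5 times.

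A pseudocount of 1 scaled CPM shrinks low gene models. It gave 4726 apart for AA1 against B1 (2238 higher, 2488 lower), 1430 for dry seed against AA1 (718 higher, 712 lower) and 9370 for seedling against dry seed (5952 higher). It gave 7024 for seedling against B1 (4705 higher, 2319 lower), 6724 for seedling against AA1 (4574 higher, 2150 lower) and 8109 for dry seed against B1 (3943 lower). A filter of 5 scaled CPM tests fewer gene models. It gave 5463 apart for AA1 against B1 (2763 lower), 1981 for dry seed against AA1 (916 higher, 1065 lower), 5984 higher for seedling against dry seed, 7296 apart for seedling against AA1 (4786 higher) and 4114 lower for dry seed against B1. With no filter beyond more than 3 counts in either library, 2463 were higher for dry seed against AA1. The interval rule gave 5615 apart for AA1 against B1 (2070 higher), 2288 for dry seed against AA1 (1048 higher, 1240 lower) and 3744 higher for dry seed against B1.

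The stage of highest level at 2-fold held 3607, 875, 3272 and 7151 gene models for B1, AA1, dry seed and seedling, and at 8-fold 884, 28, 182 and 2280. Detection at 5 CPM gave 11342, 16345 and 15727 gene models in B1, AA1 and dry seed, and at any count 37120, 40550 and 37997. Taking 100 in place of 10 gene models raised the share of counts to 70.89% in B1, 38.88% in AA1, 29.76% in dry seed and 20.57% in seedlings. The correlation of AA1 with dry seed was 0.706 among gene models with at least 10 scaled CPM in either. For the other pairs it ran from -0.079 (dry seed with seedling) to 0.366 (B1 with AA1). This filter itself lowers a correlation, since it drops gene models low in both libraries and keeps those high in 1. Thinning to the B1 depth left all counts of gene models apart within 1.5 times. The medians of the gene lists and the share without storage protein genes were not run, because no identifier matched a gene name. No paired analysis was possible because each stage has 1 library. Depth limits low levels most in B1, where a gene model at 1 scaled CPM rests on 9.36 counts, against 40.1 in AA1, 23.3 in dry seed and 42.5 in seedlings.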

Other observations

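Of the tests below, those on seed coat and axis and on sequencing depth were formulated after their values had been seen, and the patterns themselves were noticed in these data. The 247 gene models high in B1 and AA1 and low in dry seed and seedlings held 40.5% of B1 counts, 5.98% of AA1 counts, 0.92% of dry-seed counts and 0.10% of seedling counts. With total counts in place of TMM this group had 162 members. The 354 gene models high in AA1 and seedlings and low in B1 and dry seed had medians of 0.21, 4.01, 0.39 and 8.36 scaled CPM in B1, AA1, dry seed and seedlings. With total counts the group had 675 members. Another 231 were low in AA1 alone. The group highest in seedlings made up 11.4% to 14.2% of the gene models with at least 1 scaled CPM on each of the 20 chromosomes, and the group highest in B1 made up 3.92% to 6.29%. The group highest in dry seed made up 1.58% to 3.29%, and the small group highest in AA1 made up 0.21% to 0.72%. Among the 90 such gene models without a chromosome number, 11.1% were highest in dry seed. Whether these shares differ beyond chance was not tested.

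More gene models were detected in seedling cotyledons than in dry seed, by 7353 at 1 CPM. Sequencing depth was argued against as the whole explanation by the gene models with any count, a number that depends on depth: the difference was 6568 at full depth and 5999 after all libraries were thinned to the depth of B1. A few genes taking most of the counts was argued against as the whole explanation by leaving out the 264 most abundant gene models, after which the difference was 6528. A wider transcript range in the seedling cotyledon and a difference between single library preparations stay open, since the stage has 1 library.

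The 800 gene models highest in dry seed come from the only library that held seed coat and axis besides cotyledons. Counting error was argued against as the whole explanation, since unchanged libraries drawn with counting error alone gave 0 such gene models. Low levels in B1 were better resolved in that draw than in the data. RNA of seed coat and axis in the whole seed stays open. The group held 5.72% of dry-seed counts, which by itself bounds nothing, and the marker lists fixed for these tissues could not be matched to the identifiers. Transcripts made late in drying or kept while others were lost are a candidate biological explanation that was not tested.

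Neighbouring gene models shared a stage group more often than random sets matched on abundance. This was counted in each of the 8 groups of at least 500 gene models, a size chosen after the data were seen. Pairs of directly adjacent identifiers exceeded the maximum of 1000 random draws in each of the 8 groups, from 446 against 375 for the group highest in seedlings to 45 against 44 for the group low only in B1. Summed over the groups there were 968, a ratio of 1.64 to the mean of the draws. Gene models can belong to more than 1 group, so a pair can count more than once in such sums. At 2 to 5 gene models apart the sum was 2466, above the maximum of 2409 in the draws, and the ratio of the sums was 1.10. There the dry seed group (80 against 65) and the B1 group (226 against 223) passed their own maximum, and the other groups did not. Regions of more than 10 gene models sharing a profile were argued against as the account of this excess, since pairs 6 to 10 and 11 to 20 gene models apart stayed inside the range of the draws in each group (ratios of the sums 1.03 and 1.025), while shorter runs stay open. Reads shared between neighbouring copies, or 1 gene split into 2 models, stay open: 27.5% of adjacent pairs had highest levels within 2-fold of each other, against 21.5% to 31.2% for random pairs of the same groups, and stray reads on a copy would give unequal pairs too. Tandem duplicates that keep a common stage profile may also produce this pattern, and gene sequences, not used here, would be needed to tell these apart.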
